A study of Homo sapiens with 36 samples.

How the data were processed

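Gene expression was measured on single-colour Illumina bead arrays in DU145, PC-3 and 22Rv1 cells, with biotinylated cRNA made from total RNA. Per the labels, cells were kept in normoxia or at 0.2% oxygen for 24 h, with 1 µM vorinostat or solvent for 24 h, 3 arrays per combination and 36 in all. The sample titles name solvent where the sample characteristics say untreated; the arrays are called solvent arrays here. The resistance labels and the statement that vorinostat radiosensitised DU145 alone come from the study's design text, and neither was measured in these samples. Groups were taken from the labels.

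Per the file headers, the deposited non-normalized values give the average bead signal of each probe as an intensity on the linear scale. Bead data were summarised with BeadStudio 3.1.3.0 per the submitters' processing notes. The lowest signal of an array lies between 64.4 and 90.1, so no background subtraction is visible in the values. Per the file headers, the same deposited file gives a detection p-value for each probe and array. The deposited processed values are, by their numbers, an intensity on the linear scale after quantile normalization over the 36 arrays: the ranks within each array equal those of the non-normalized signal (lowest rank correlation 1), and the medians lie between 110.8 and 110.9. Any further step that the authors applied, and any filter, are not given in the sources used here. No 2 arrays hold identical values (0 identical pairs), and no column of sample values was left unused.

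The non-normalized signals were background corrected and quantile normalized over all arrays with neqc in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8), with an offset of 16 and the background distribution inferred from the detection p-values, and put on the log2 scale. Figures were drawn with matplotlib 3.10.9. Of 47323 probes, 30113 carry 1 gene symbol (30074 by Entrez ID), 8 carry several and 17202 carry none, which gives 20046 symbols with a probe. A probe was used if its detection p was below 0.01 on at least 3 of the 36 arrays, which 21376 probes met, 16501 of them with 1 symbol. The probe with the highest mean stood for its gene, which left 12360 genes. For 3285 genes more than 1 probe passed. Their probes were called in opposite directions for 6 to 24 genes (vorinostat), 2 to 5 genes (hypoxia), 12 and 30 genes (drug effect between lines) and 91 and 117 genes (lines without drug). The 4875 detected probes with no or several symbols are counted only in the closing part.

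Depth on arrays is signal over background: 30.1% to 35.7% of the probes were above background on an array, the median signal was 92.5 to 126.6 and the 95th percentile 878.1 to 1413.6. The 3 arrays per group limit the precision. On simulated data with 67 genes per size and the spread of these arrays, 94.0% and 98.5% of genes changed by 1 log2 unit in DU145 were called for vorinostat in normoxia and hypoxia, and 43.3% and 34.3% of genes changed by 0.5.

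One limma model with 12 group means was fitted to the 36 arrays, so that all groups share the spread of a gene (29.5 degrees of freedom after moderation). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12360 genes of a comparison. Comparisons were vorinostat against solvent per line and oxygen level, hypoxia against normoxia on solvent arrays, the drug effect in hypoxia minus that in normoxia, the drug effect in DU145 minus that in PC-3 or 22Rv1 (means of both oxygen levels), and DU145 against each other line in normoxia with solvent. The drug and hypoxia comparisons of a line share their solvent arrays, as do the comparisons of DU145 with the other lines. The main model, the named-gene rule, the gene lists and all alternatives except 2 were set before the data were examined.

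The 25 gene lists (519 entries, 438 of them tested, 428 distinct genes) were written from general knowledge: hypoxia-induced genes, glycolysis, unfolded protein and integrated stress response, histone deacetylases, histone genes, metallothioneins, cyclin-dependent kinase inhibitors, G2 and mitosis, DNA replication, homologous recombination and Fanconi anaemia, non-homologous end joining, DNA damage signalling, base and nucleotide excision and mismatch repair, p53 targets, apoptosis regulators, antioxidant and thioredoxin genes, androgen targets, epithelial markers, mesenchymal markers, neuronal and neuroendocrine genes, cholesterol synthesis, interferon-stimulated genes, NF-kappaB and inflammatory genes, ribosomal proteins, and markers of other cell types. Each list was tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted over the 25 lists of a comparison. The test was repeated with the correlation estimated from the data. Separately, fry tested each list against no change, not against other genes.

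Genes were named by a fixed rule. It takes, for vorinostat in each line, the 6 largest rises and 6 largest falls among genes called at both oxygen levels in the same direction whose drug arrays lie beyond all solvent arrays. For hypoxia and for the lines without drug it takes the 6 largest rises and falls among called genes with groups that do not overlap, and for the drug effect between oxygen levels the 3 largest each way. For DU145-specific genes it takes the 10 largest rises and falls, and from each list up to 3 called members with the largest change, of which the first 2 are printed for lists that shifted. A last part names 14 genes whatever their test. Of these, HDAC1, HDAC2, HDAC3, HDAC6, CDKN1A, TYMS, TXNIP, VEGFA, CHEK1 and CCNB1 are given for vorinostat, a choice made after their values were seen, KLK3 did not pass the detection filter, and 3 are not reported here, nor are 3 genes that other parts of the rule name. Genes given as a bound were ranked by a fitted change that rests on a group not above background. Other members were left out for length alone, and probes without an established gene name were passed over.

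A bound of "at least N-fold" compares the mean log2 level of the detected group with that of the other group, each array of which is taken at no less than the lowest level called above background on it. Alternatives were no background correction, the authors' processed values, quantile normalization within each line, median scaling, cyclic loess, no filter, detection on all 36 arrays, every probe tested, the 12 arrays of a line alone, array weights, a replicate block, and each array left out in turn. Chosen after the data were seen were 1 weight per cell line and a limit of 1.5-fold for the DU145-specific genes. The pairing by replicate number was checked through the correlation, across genes, of the deviations of arrays with the same number from their group means. All 3 correlations exceeded 0.1 in 3 of 9 comparisons: vorinostat in DU145 in hypoxia (0.193 to 0.232), vorinostat in PC-3 in normoxia (0.300 to 0.468) and hypoxia in PC-3 (0.151 to 0.353). There the data, not the labels, hint at pairing. The reported counts are unpaired, and pairing changed those of these 3 comparisons by less than 1.5 times. The procedure was tested on simulated data with known changes and each line's measured spread. A list shifted by 0.5 was called by camera, and no unshifted list was. With the shared spread the false share was above the 5% aimed at in DU145 and PC-3. It stands by the counts but describes simulated calls, which were fewer. With 1 weight per line it was 4.33% to 8.21% in DU145, 6.17% to 8.16% in PC-3 and 5.25% to 7.05% in 22Rv1, so the shared spread is not shown to be the whole cause. These simulations were chosen after a first had shown unequal spread between lines.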

Results

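The data are 36 single-colour bead arrays of total RNA from 3 human prostate cancer cell lines, labelled as radiation resistant (DU145) or radiation sensitive (PC-3 and 22Rv1). Each line was grown in normoxia or in hypoxia (0.2% oxygen, 24 h), with the histone deacetylase inhibitor vorinostat (1 µM, 24 h) or with its solvent. This gives 12 groups of 3 arrays. The cells were sampled before irradiation. Between 14242 probes (DU145 normoxia solvent 1) and 16900 probes (PC-3 normoxia vorinostat 2) of 47323 were above background on an array, and 12360 genes were tested. The 95th percentile of the signal was 9.49 to 12.1 times the array's median. The correlation between replicates was 0.985 to 0.995, and the median standard deviation of a gene between replicates was 0.174 (DU145), 0.191 (PC-3) and 0.134 (22Rv1) on the log2 scale. Differences between the lines carried most of the variance, with 51.1% on the first principal component and 30.4% on the second. The replicates are not stated to be separate cultures, so every p-value measures only the spread between these samples, which may be technical.

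Values are log2 changes ± standard error from limma, followed by the adjusted p where one is given. For vorinostat they are means over both oxygen levels (6 vorinostat against 6 solvent arrays), for hypoxia 3 solvent arrays against 3. A gene above background on no array of a group is given as "at least N-fold", and a list's median "with bounds" takes such genes at that bound and leaves out genes above background in neither group. Called means an adjusted p under 0.05. Counts adjusted over the list alone are given where they differ. Each called gene named for vorinostat lay beyond the solvent mean of its oxygen level on 6 of 6 vorinostat arrays, except HDAC3 and CCNB1 in DU145 and HDAC1 and HDAC6 in PC-3, with 5 of 6. Each called gene named for hypoxia or between the solvent-treated lines lay beyond the other group's mean on 3 of 3 arrays.

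The first comparison asks what vorinostat changed in DU145, the line that the study's design text describes as radiosensitised by the drug. The largest rises were in VGF (3.40 ± 0.16, adjusted p = 9.1e-17), which encodes a neurosecretory protein, and TMSB15A (at least 9.68-fold higher, adjusted p = 2.9e-18), which encodes an actin-binding thymosin. Further large rises were in CCNA1 (3.30 ± 0.21, detected on 2 of 6 solvent arrays), a cyclin, and HLA-DMB (3.26 ± 0.10), a peptide-loading factor of the class II antigen pathway (largest adjusted p = 5.0e-14). AADACP1 (at least 5.50-fold higher, adjusted p = 7.4e-15), a pseudogene, also rose. The largest falls were in FGB (-3.05 ± 0.19), the fibrinogen beta chain, NRP1 (-2.59 ± 0.14), a semaphorin and growth factor co-receptor, CAP2 (-2.31 ± 0.13), an actin regulator, and MALL (-2.27 ± 0.11), a membrane raft protein (largest adjusted p = 4.1e-14). TXNIP (2.46 ± 0.15, adjusted p = 2.1e-14), which encodes an inhibitor of thioredoxin, and CDKN1A (1.37 ± 0.16, adjusted p = 1.9e-08), the cell cycle inhibitor p21, rose, while TYMS (-1.59 ± 0.09, adjusted p = 2.4e-15), thymidylate synthase, fell.

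Among the drug's target enzymes in DU145, HDAC1 (1.09 ± 0.06, adjusted p = 1.1e-15) and HDAC3 (0.37 ± 0.08, adjusted p = 4.1e-04) rose, and HDAC2 (0.11 ± 0.06, adjusted p = 0.126) and HDAC6 (-0.01 ± 0.10, adjusted p = 0.920) were not called; the sign of HDAC6 turned with array weights (0.01), cyclic loess (0.04) and median scaling (0.11). The angiogenic factor VEGFA (-0.62 ± 0.13, adjusted p = 2.1e-04), the checkpoint kinase CHEK1 (-0.77 ± 0.08, adjusted p = 2.6e-09) and the mitotic cyclin CCNB1 (-0.25 ± 0.08, adjusted p = 0.00757) fell; the call for CCNB1 ended with median scaling (adjusted p = 0.137, 0.00463 to 0.137 over the alternatives). Of the histone genes, 16 rose, 2 fell and 4 were not called of 22 (median log2 change 0.73, or 0.67 with bounds, camera adjusted p = 0.00161, adjusted p = 0.586 with an estimated correlation). They include H2AC8 (at least 2.08-fold higher) and H4C14 (1.55 ± 0.15). Of the metallothioneins, which bind zinc and other metals, 8 rose, 0 fell and 0 were not called of 8 (median log2 change 1.60, or 0.92 with bounds, camera adjusted p = 1.6e-05, adjusted p = 0.388 with an estimated correlation). They include MT1X (2.07 ± 0.12) and MT3 (at least 2.05-fold higher). Of the DNA replication genes, 2 rose, 23 fell and 12 were not called of 37, or 3 and 23 adjusted over the list alone (median log2 change -0.32, camera adjusted p = 3.9e-04, adjusted p = 0.519 with an estimated correlation). They include the helicase subunit MCM5 (-1.09 ± 0.14) beside TYMS. Of the G2 and mitosis genes, 4 rose, 16 fell and 14 were not called of 34, or 4 and 17 adjusted over the list alone (median log2 change -0.22, camera adjusted p = 0.0208, adjusted p = 0.670 with an estimated correlation). They include the transcription factor FOXM1 (-1.02 ± 0.11) and the phosphatase CDC25B (-0.82 ± 0.10).

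In DU145, 5035 genes were called in normoxia (2742 higher, 2293 lower) and 5107 in hypoxia (2734 higher, 2373 lower), of which 2636 and 2709 changed by at least 1.5-fold. At both oxygen levels 3754 genes moved the same way (2070 higher, 1684 lower) and 20 were called in opposite directions, against 1034 expected if the calls were independent. The share called higher in hypoxia was 53.5%, or 68.5% with median scaling. In 47.2% (normoxia) and 49.8% (hypoxia) of the tested genes the vorinostat and solvent arrays did not overlap, against 10% by chance. Simulations gave means of 3656 to 3671 DU145 calls, 5.35% to 5.86% of them false.

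In PC-3, labelled radiation sensitive, the largest rises were in TUBB2B (2.90 ± 0.32, adjusted p = 1.3e-08, detected on 5 of 6 solvent arrays), a neuronal beta-tubulin, KIF5C (2.70 ± 0.11, adjusted p = 2.7e-17, detected on 3 of 6 solvent arrays), a kinesin heavy chain, and FABP4 (2.44 ± 0.16, adjusted p = 4.1e-13), a fatty acid carrier. KRT34 (2.44 ± 0.26), a hair keratin, LUM (2.43 ± 0.23, detected on 4 of 6 solvent arrays), a matrix proteoglycan, and RGS4 (2.25 ± 0.17), a regulator of G protein signalling, also rose (largest adjusted p = 6.4e-09). Falls were largest in TH (-2.05 ± 0.15), tyrosine hydroxylase, AVEN (-1.92 ± 0.15, detected on 1 of 6 vorinostat arrays), an apoptosis inhibitor, SERPINH1 (-1.83 ± 0.11), a collagen chaperone, and DNLZ (-1.82 ± 0.08), a mitochondrial chaperone partner (largest adjusted p = 3.4e-11). CDKN1A (1.18 ± 0.16, adjusted p = 6.3e-07) rose and TYMS (-0.87 ± 0.09, adjusted p = 2.7e-09) fell, as in DU145. CHEK1 (-0.47 ± 0.08, adjusted p = 2.5e-05), CCNB1 (-0.52 ± 0.08, adjusted p = 3.8e-06) and HDAC6 (-0.37 ± 0.10, adjusted p = 0.00242) fell.

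No change was called in PC-3 for HDAC2 (0.13 ± 0.06, adjusted p = 0.0899), HDAC3 (0.18 ± 0.08, adjusted p = 0.0851), TXNIP (-0.02 ± 0.15, adjusted p = 0.941) and VEGFA (-0.07 ± 0.13, adjusted p = 0.723); the sign of TXNIP turned with array weights (0.03) and cyclic loess (0.05), and that of VEGFA without single arrays (up to 0.05). HDAC1 (0.15 ± 0.06, adjusted p = 0.0379) passed narrowly. Its call ended with median scaling (adjusted p = 0.297, 0.00179 to 0.297 over the alternatives), with 1 weight per line (0.0773), with the 12 arrays of PC-3 alone (0.134), and without any of 8 arrays: hypoxia solvent 2 (0.117) and 3 (0.0587), hypoxia vorinostat 1 (0.0763) and 2 (0.0569), normoxia solvent 2 (0.0596) and 3 (0.0785), and normoxia vorinostat 1 (0.0934) and 2 (0.0909).

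Of the cyclin-dependent kinase inhibitors in PC-3, 4 rose, 0 fell and 3 were not called of 7 (median log2 change 0.42, camera adjusted p = 0.0441, adjusted p = 0.239 with an estimated correlation). They include CDKN2D (0.74 ± 0.10) beside CDKN1A. Among the DNA replication genes, 1 rose, 25 fell and 11 were not called of 37, or 1 and 27 adjusted over the list alone (median log2 change -0.34, camera adjusted p = 1.5e-05, adjusted p = 0.239 with an estimated correlation). They include MCM4 (-0.74 ± 0.10) beside TYMS. Among G2 and mitosis genes, 1 rose, 18 fell and 15 were not called of 34, or 1 and 19 adjusted over the list alone (median log2 change -0.32, camera adjusted p = 2.7e-05, adjusted p = 0.365 with an estimated correlation). They include FOXM1 (-0.80 ± 0.11) and KIF20A (-0.73 ± 0.10), a mitotic kinesin. Of the homologous recombination and Fanconi anaemia genes, 0 rose, 10 fell and 10 were not called of 20 (median log2 change -0.29, camera adjusted p = 0.0159, adjusted p = 0.239 with an estimated correlation). They include NBN (-0.68 ± 0.10) and RAD51AP1 (-0.67 ± 0.08), which act in the repair of double-strand breaks. Of the epithelial markers, 8 rose, 1 fell and 7 were not called of 16 (median log2 change 0.40, or 0.69 with bounds, camera adjusted p = 0.0102, adjusted p = 0.239 with an estimated correlation). They include the junction genes CLDN7 (1.71 ± 0.17) and JUP (1.10 ± 0.11). None of these 5 list calls held with an estimated correlation. In PC-3, 3176 genes were called in normoxia (1523 higher, 1653 lower) and 3506 in hypoxia (1796 higher, 1710 lower), of which 1370 and 1526 changed by at least 1.5-fold. At both oxygen levels 2166 moved the same way (1070 higher, 1096 lower), and 6 moved in opposite directions, against 451 expected. With median scaling the share called higher in hypoxia moved from 51.2% to 30.5%. The groups did not overlap in 33.1% (normoxia) and 35.8% (hypoxia) of the genes, against 10% by chance. Simulations gave means of 2114 to 2163 PC-3 calls, 10.6% to 11.8% of them false.

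In 22Rv1, also labelled radiation sensitive, the largest rises were in CGA (3.10 ± 0.12, adjusted p = 2.8e-19), which encodes the alpha subunit of the gonadotropins, PDK4 (2.94 ± 0.14, adjusted p = 8.5e-17), an inhibitor of pyruvate dehydrogenase, and FSD1 (at least 6.83-fold higher, adjusted p = 1.8e-20). The interferon-induced IFI6 (2.76 ± 0.15), ATP6V1G2 (at least 5.47-fold higher), a proton pump subunit, and TCIM (at least 4.46-fold higher) also rose (largest adjusted p = 3.6e-15). Among the largest falls were TYMS (-2.34 ± 0.09, adjusted p = 2.8e-19), MCM5 (-2.14 ± 0.14, adjusted p = 2.1e-13), CYP1B1 (-2.08 ± 0.15, detected on 5 of 6 vorinostat arrays), a cytochrome P450, and CDC45 (-1.95 ± 0.08) and UHRF1 (-1.92 ± 0.13), which act in replication and in the upkeep of DNA methylation (largest adjusted p = 6.0e-13). CHEK1 (-1.30 ± 0.08, adjusted p = 3.5e-14) and CCNB1 (-0.94 ± 0.08, adjusted p = 2.7e-11) also fell. CDKN1A (0.60 ± 0.16, adjusted p = 0.00266) rose, as did HDAC1 (0.25 ± 0.06, adjusted p = 6.0e-04) and HDAC3 (0.33 ± 0.08, adjusted p = 0.00166), whose calls ended with median scaling (adjusted p = 0.0938 and 0.0513, 3.2e-05 to 0.0938 over the alternatives for HDAC1 and 7.4e-05 to 0.0513 over the alternatives for HDAC3). HDAC2 (-0.01 ± 0.06, adjusted p = 0.929), HDAC6 (0.03 ± 0.10, adjusted p = 0.833), TXNIP (0.15 ± 0.15, adjusted p = 0.454) and VEGFA (-0.22 ± 0.13, adjusted p = 0.197) were not called; HDAC2 changed sign with cyclic loess (0.02) and HDAC6 without single arrays (down to -0.03).

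Lists of DNA replication, mitosis, homologous recombination and damage signalling genes fell in 22Rv1. Of the DNA replication genes, 0 rose, 34 fell and 3 were not called of 37 (median log2 change -1.17, camera adjusted p = 1.9e-26, adjusted p = 2.0e-04 with an estimated correlation). Among the G2 and mitosis genes, 0 rose, 32 fell and 2 were not called of 34 (median log2 change -0.62, camera adjusted p = 9.0e-15, adjusted p = 0.0496 with an estimated correlation). They include the phosphatase CDC25A (-1.49 ± 0.09) and FOXM1 (-1.23 ± 0.11). Among the homologous recombination and Fanconi anaemia genes, 0 rose, 16 fell and 4 were not called of 20, or 0 and 17 adjusted over the list alone (median log2 change -0.82, or -0.91 with bounds, camera adjusted p = 3.8e-10, adjusted p = 9.7e-05 with an estimated correlation). They include the nuclease EXO1 (-1.79 ± 0.08) and BRCA1 (-1.45 ± 0.10). Of the DNA damage signalling genes, 1 rose, 8 fell and 2 were not called of 11 (median log2 change -0.66, camera adjusted p = 2.9e-04, adjusted p = 0.0120 with an estimated correlation). They include the replication fork protector TIMELESS (-1.62 ± 0.06) beside CHEK1. Of the metallothioneins, 7 rose, 0 fell and 1 was not called of 8 (median log2 change 1.15, camera adjusted p = 2.0e-05, adjusted p = 0.0809 with an estimated correlation). They include MT3 (1.81 ± 0.14, detected on 3 of 6 solvent arrays) and MT2A (1.22 ± 0.09). Of the neuronal and neuroendocrine genes, 10 rose, 0 fell and 7 were not called of 17, or 10 and 1 adjusted over the list alone (median log2 change 0.48, camera adjusted p = 0.00191, adjusted p = 0.0809 with an estimated correlation). They include the vesicle proteins SYT11 (at least 3.62-fold higher) and CHGB (1.79 ± 0.09). Of the mesenchymal markers, 6 rose, 0 fell and 7 were not called of 13 (median log2 change 0.21, or 0.36 with bounds, camera adjusted p = 0.0120, adjusted p = 0.160 with an estimated correlation). They include CAV1 (1.45 ± 0.14, detected on 2 of 6 solvent arrays) and LGALS1 (1.44 ± 0.07). In 22Rv1, 3872 genes were called in normoxia (2025 higher, 1847 lower) and 4125 in hypoxia (2039 higher, 2086 lower), of which 1937 and 2075 changed by at least 1.5-fold. At both oxygen levels 2995 moved the same way (1526 higher, 1469 lower), and 4 moved in opposite directions, against 646 expected. The share called higher in hypoxia was 49.4%, or 39.1% with median scaling. The groups did not overlap in 53.3% (normoxia) and 49.9% (hypoxia) of the genes, against 10% by chance, and 1.83% to 2.57% of the calls were false on simulated data.

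Several lists had called genes but no shift against other genes under vorinostat in any line. In DU145, 1 of 8 non-homologous end joining genes rose and 3 fell (1 and 4 adjusted over the list alone), 6 of 20 genes of base and nucleotide excision and mismatch repair rose and 10 fell, 6 of 19 p53 target genes rose and 4 fell, and 6 of 22 apoptosis regulators rose and 6 fell (7 and 6 adjusted over the list alone). In the same line 4 of 17 antioxidant and thioredoxin genes rose and 7 fell, 7 of 18 genes of the unfolded protein and integrated stress response rose and 7 fell, 2 of 11 histone deacetylases rose and 2 fell, and 1 of 19 ribosomal protein genes rose and 4 fell (0 and 4 adjusted over the list alone). For markers of fibroblasts, endothelium and leukocytes, 2 of 6 genes rose and 0 fell. The stress response, histone deacetylase and apoptosis lists had a median, mean and test of unequal sign there. The smallest camera adjusted p of these lists was 0.0770 over the 3 lines, for the last list in PC-3, where 3 of 6 genes rose and 0 fell; with median scaling it was 0.0201. Median scaling also brought the NF-kappaB and inflammatory genes of PC-3 (adjusted p = 0.0171 in place of 0.0770) and the interferon-stimulated genes of 22Rv1 (0.0294 in place of 0.0822) past the threshold, towards higher levels.

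**Figure D1:**
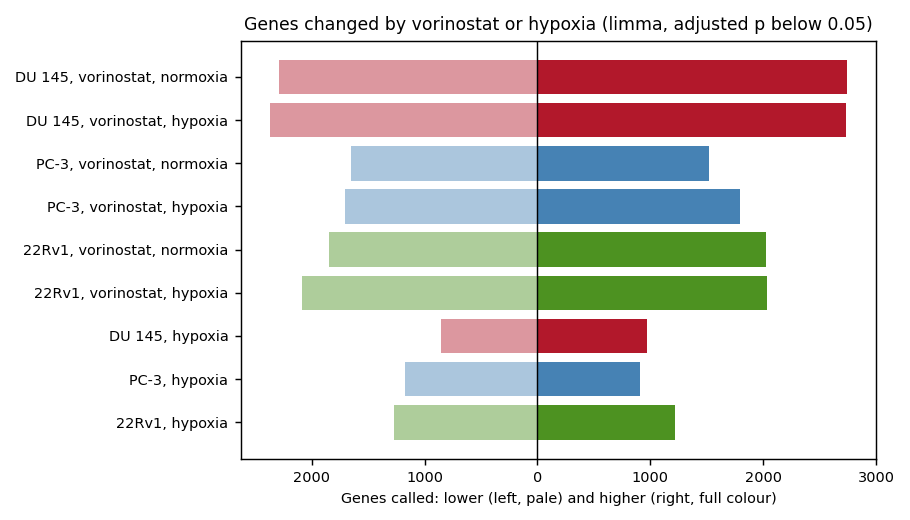
Numbers of genes called higher (bars to the right) and lower (bars to the left) for vorinostat against solvent in each line and oxygen level, and for hypoxia against normoxia without drug in each line, from limma at an adjusted p under 0.05. The bars run from 854 genes (lower with hypoxia in DU145) to 2742 (higher with vorinostat in DU145 in normoxia).

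Genes that vorinostat moved at both oxygen levels overlapped between the lines. In all 3 lines 306 genes rose and 359 fell, against 22.1 and 17.7 expected if the calls were independent. On the mean of both oxygen levels CDKN1A rose and TYMS and CHEK1 fell in each line. DU145 and PC-3 had 598 rises and 618 falls in common and 51 genes in opposite directions, DU145 and 22Rv1 had 675, 588 and 107, and PC-3 and 22Rv1 had 445, 536 and 52. Across genes, which are not independent replicates, the mean log2 changes of 2 lines had a Pearson correlation of 0.55 (DU145 and PC-3), 0.45 (DU145 and 22Rv1) and 0.48 (PC-3 and 22Rv1).

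**Figure D2:**
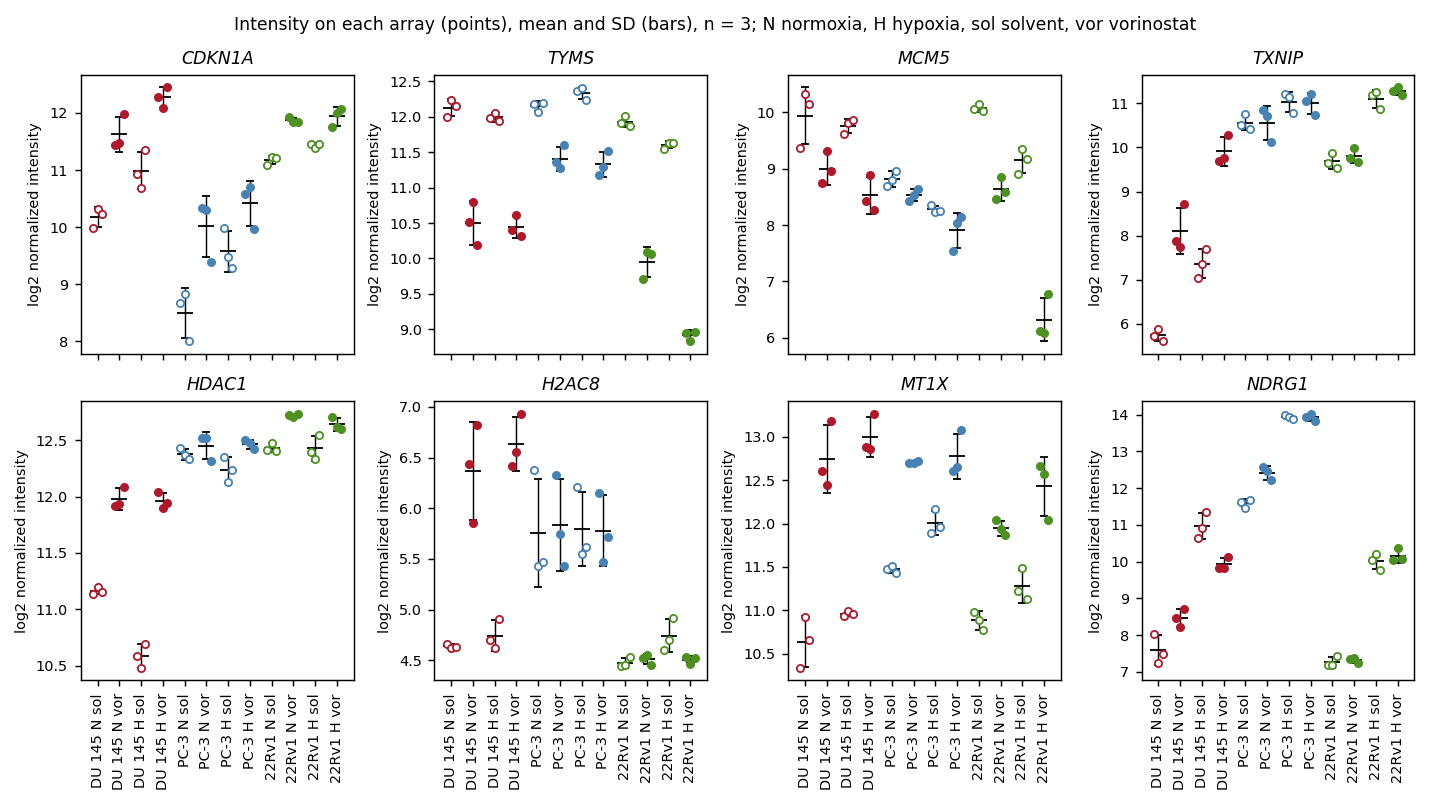
Log2 normalized intensity of 8 genes in the 12 groups of cell line, oxygen level and drug (points are single arrays, bars the mean and standard deviation of 3 arrays). NDRG1 in DU145 stands at 7.58 ± 0.41 in normoxia with solvent and at 10.97 ± 0.35 in hypoxia with solvent.

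The hypoxia comparisons ask what low oxygen changed without drug. In DU145 the largest rises were in KISS1R (3.84 ± 0.17, adjusted p = 3.7e-16), IGFBP3 (3.64 ± 0.19, adjusted p = 1.0e-14), NDRG1 (3.39 ± 0.17, adjusted p = 4.9e-15), a stress-response gene, and ALDOC (3.14 ± 0.18, adjusted p = 1.6e-13), an aldolase. FGF11 (2.82 ± 0.21, detected on 1 of 3 normoxia arrays) and PFKFB4 (2.82 ± 0.17) also rose (largest adjusted p = 5.9e-11). The largest falls were in HIF1A (-1.95 ± 0.22, detected on 2 of 3 hypoxia arrays), a subunit of the hypoxia-inducible factor, the small nucleolar RNAs SNORD14D (-1.68 ± 0.18, detected on 1 of 3 hypoxia arrays) and SNORD31 (-1.40 ± 0.18, detected on 2 of 3 hypoxia arrays), and the transcription factor subunit TAF9B (-1.27 ± 0.15); SNORA24 (at least 1.99-fold lower) also fell (largest adjusted p = 2.3e-06). Of the hypoxia-induced genes, 21 rose, 0 fell and 3 were not called of 24 (median log2 change 1.44, or 1.38 with bounds, camera adjusted p = 1.2e-42, adjusted p = 1.4e-07 with an estimated correlation). Of the glycolysis enzymes and glucose transporters, 15 rose, 0 fell and 3 were not called of 18, or 16 and 0 adjusted over the list alone (median log2 change 0.85, camera adjusted p = 5.1e-24, adjusted p = 2.8e-06 with an estimated correlation). They include ENO2 (1.65 ± 0.15) beside ALDOC. Of the cholesterol synthesis genes, 11 rose, 0 fell and 6 were not called of 17, or 12 and 0 adjusted over the list alone (median log2 change 0.53, camera adjusted p = 7.7e-11, adjusted p = 0.00345 with an estimated correlation). They include INSIG1 (1.47 ± 0.14) and HMGCS1 (1.35 ± 0.18). Of the homologous recombination and Fanconi anaemia genes, 0 rose, 4 fell and 16 were not called of 20, or 0 and 7 adjusted over the list alone (median log2 change -0.17, camera adjusted p = 0.0321, adjusted p = 0.116 with an estimated correlation). They include RAD51D (-0.74 ± 0.21, detected on 2 of 3 hypoxia arrays) and RAD54L (-0.55 ± 0.13). The call of RAD51D ended with the 12 arrays of DU145 alone (adjusted p = 0.0601, 0.00311 to 0.0601 over the alternatives) and without hypoxia solvent 1 (0.0687), hypoxia solvent 2 (0.0677) or normoxia solvent 3 (0.116). In DU145 1823 genes were called (969 higher, 854 lower), of which 717 changed by at least 1.5-fold. The groups did not overlap in 29.1% of the genes, against 10% by chance, and 8.19% to 9.40% of the calls were false on simulated data.

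In PC-3 the largest rise with hypoxia was in RNA28SN5 (4.74 ± 1.35, adjusted p = 0.0141, detected on 2 of 3 normoxia arrays), a probe for 28S ribosomal RNA, followed by ANGPTL4 (4.19 ± 0.23, adjusted p = 1.7e-14), SCNN1G (3.17 ± 0.15, adjusted p = 4.5e-15), and DEPP1 (2.89 ± 0.15, detected on 2 of 3 normoxia arrays), ITPR1 (2.77 ± 0.19) and SLC2A1 (2.41 ± 0.13), the last of which is a glucose transporter (largest adjusted p = 3.8e-12). The call of RNA28SN5 ended without normoxia solvent 1 (log2 change 3.18, adjusted p = 0.150) and with the 12 arrays of PC-3 alone (0.0600, 0.00475 to 0.0600 over the alternatives). Falls were largest in HIF1A (-1.46 ± 0.22), HSPBAP1 (-1.19 ± 0.15) and RNFT2 (-1.08 ± 0.16); GPCPD1 (at least 1.76-fold lower), a phosphodiesterase, also fell (largest adjusted p = 1.5e-05). Among the hypoxia-induced genes, 23 rose, 0 fell and 1 was not called of 24 (median log2 change 1.57, camera adjusted p = 2.7e-52, adjusted p = 2.0e-08 with an estimated correlation). They include NDRG1 (2.36 ± 0.17) beside ANGPTL4. Among the glycolysis enzymes and glucose transporters, 14 rose, 1 fell and 3 were not called of 18 (median log2 change 0.58, or 0.65 with bounds, camera adjusted p = 1.7e-14, adjusted p = 1.5e-04 with an estimated correlation). They include ENO2 (1.60 ± 0.15) beside SLC2A1. Among the DNA replication genes, 0 rose, 8 fell and 29 were not called of 37, or 0 and 10 adjusted over the list alone (median log2 change -0.14, camera adjusted p = 0.0188, adjusted p = 0.472 with an estimated correlation). They include POLE2 (-0.62 ± 0.12) and RFC3 (-0.57 ± 0.13), the second of which has another probe of opposite sign; with median scaling the adjusted p of this list was 0.0605. Among the mesenchymal markers, 2 rose, 0 fell and 11 were not called of 13, or 3 and 0 adjusted over the list alone (median log2 change 0.27, camera adjusted p = 0.0188, adjusted p = 0.371 with an estimated correlation). They include S100A4 (0.55 ± 0.17) and LGALS1 (0.37 ± 0.10). The call of S100A4 ended with median scaling (adjusted p = 0.0508), array weights (0.0647) and 1 weight per line (0.0974, 0.00113 to 0.0974 over the alternatives), and without hypoxia solvent 1 (0.117) or 3 (0.0746) or normoxia solvent 2 (0.0727) or 3 (0.0847). That of LGALS1 ended with median scaling (0.149, 0.00179 to 0.149 over the alternatives) and without normoxia solvent 3 (0.0606). In PC-3 2086 genes were called (908 higher, 1178 lower), of which 761 changed by at least 1.5-fold. The share called higher was 43.5%, or 54.2% with cyclic loess. The groups did not overlap in 27.9% of the genes, against 10% by chance, and 11.3% to 12.5% of the calls were false on simulated data.

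In 22Rv1 the largest rises with hypoxia were in MT3 (at least 36.4-fold higher, adjusted p = 9.7e-20), a metallothionein, RNA28SN5 (5.04 ± 1.35, adjusted p = 0.00771), ADM (4.42 ± 0.17, adjusted p = 2.3e-18), the vasodilator adrenomedullin, PFKFB4 (4.24 ± 0.17, adjusted p = 2.3e-18) and BHLHE40 (3.89 ± 0.11, adjusted p = 6.3e-22), a transcriptional repressor. In DU145 RNA28SN5 was not called (3.06 ± 1.35, adjusted p = 0.134). The largest falls were in OVOL2 (-1.33 ± 0.19), an epithelial transcription factor, CDCA7 (-1.28 ± 0.13), TAF9B (-1.25 ± 0.15) and FAM72B (-1.18 ± 0.15), with adjusted p = 3.6e-06 or less. Of the hypoxia-induced genes, 23 rose, 0 fell and 1 was not called of 24 (median log2 change 2.44, camera adjusted p = 2.0e-61, adjusted p = 4.0e-09 with an estimated correlation). Of the glycolysis enzymes and glucose transporters, 14 rose, 0 fell and 4 were not called of 18, or 15 and 0 adjusted over the list alone (median log2 change 1.03, camera adjusted p = 3.9e-22, adjusted p = 5.7e-06 with an estimated correlation). They include ALDOC (2.82 ± 0.18) and HK2 (2.70 ± 0.16). Of the DNA replication genes, 0 rose, 22 fell and 15 were not called of 37, or 0 and 26 adjusted over the list alone (median log2 change -0.44, camera adjusted p = 4.7e-11, adjusted p = 0.0156 with an estimated correlation). They include GINS4 (-1.13 ± 0.30) and MCM5 (-0.93 ± 0.20). Among the homologous recombination and Fanconi anaemia genes, 0 rose, 12 fell and 8 were not called of 20, or 0 and 13 adjusted over the list alone (median log2 change -0.46, camera adjusted p = 3.3e-07, adjusted p = 4.3e-04 with an estimated correlation). They include FANCE (-0.91 ± 0.12) and FANCG (-0.82 ± 0.17). Of the cholesterol synthesis genes, 0 rose, 6 fell and 11 were not called of 17, or 0 and 9 adjusted over the list alone (median log2 change -0.35, camera adjusted p = 0.00485, adjusted p = 0.185 with an estimated correlation). They include MVK (-0.86 ± 0.17) and NSDHL (-0.52 ± 0.10).

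Other lists that shifted with hypoxia in 22Rv1 did so with the preset correlation only. Of the epithelial markers, 5 rose, 0 fell and 11 were not called of 16 (median log2 change 0.33, camera adjusted p = 0.00503, adjusted p = 0.169 with an estimated correlation). They include DSP (2.10 ± 0.22) and KRT8 (0.74 ± 0.14). Of the mesenchymal markers, 4 rose, 0 fell and 9 were not called of 13 (median log2 change 0.11, or 0.42 with bounds, camera adjusted p = 0.0322, adjusted p = 0.227 with an estimated correlation). They include S100A4 (1.32 ± 0.17) and LGALS1 (1.14 ± 0.10). Of the metallothioneins, 1 rose, 0 fell and 7 were not called of 8, or 2 and 0 adjusted over the list alone (median log2 change 0.22, camera adjusted p = 0.0201, adjusted p = 0.380 with an estimated correlation). Of the G2 and mitosis genes, 0 rose, 6 fell and 28 were not called of 34, or 0 and 10 adjusted over the list alone (median log2 change -0.22, camera adjusted p = 0.00503, adjusted p = 0.486 with an estimated correlation). They include CDC25A (-0.72 ± 0.13) and UBE2C (-0.49 ± 0.12), the first of which has another probe of opposite sign. Of the DNA damage signalling genes, 0 rose, 4 fell and 7 were not called of 11, or 1 and 4 adjusted over the list alone (median log2 change -0.18, camera adjusted p = 0.0322, adjusted p = 0.169 with an estimated correlation). They include CHEK1 (-0.86 ± 0.11) and RAD9A (-0.73 ± 0.17). In 22Rv1 2492 genes were called (1223 higher, 1269 lower), of which 973 changed by at least 1.5-fold. With median scaling the share called higher moved from 49.1% to 37.3%. The groups did not overlap in 45.0% of the genes, against 10% by chance, and 2.16% to 3.06% of the calls were false on simulated data. In all 3 lines 217 genes rose with hypoxia and 256 fell, against 7.04 and 8.36 expected if the calls were independent.

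**Figure D3:**
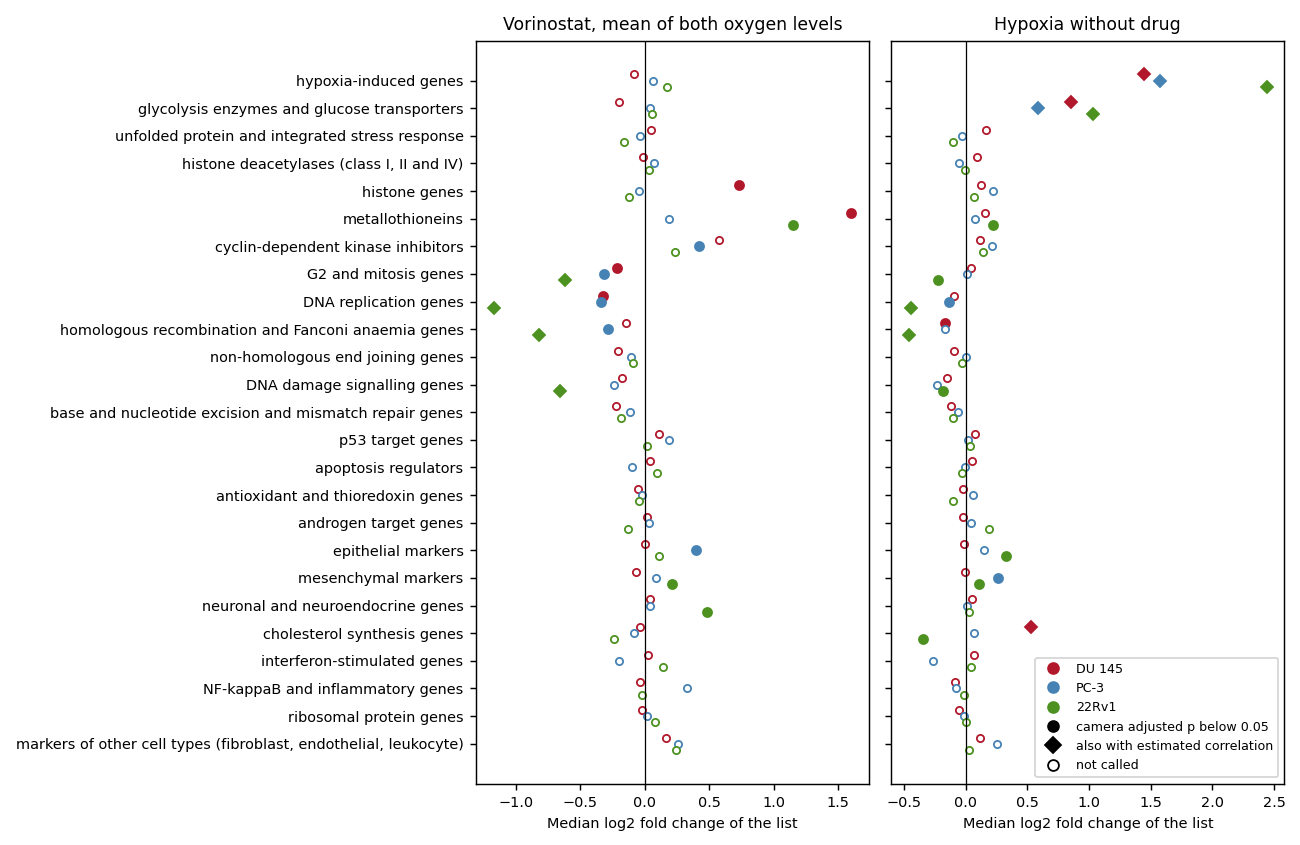
Median log2 change of each gene list with vorinostat (left, mean of both oxygen levels) and with hypoxia (right) in the 3 lines. Open symbols are lists with no call, filled symbols have a camera adjusted p under 0.05, and diamonds keep the call with an estimated correlation. The median of the DNA replication genes with vorinostat is -1.17 in 22Rv1, -0.32 in DU145 and -0.34 in PC-3.

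Whether oxygen changed the effect of vorinostat was tested as the drug effect in hypoxia minus that in normoxia. DU145 had a negative difference in KISS1R (-2.18 ± 0.24, adjusted p = 5.4e-06), NDRG1 (-1.92 ± 0.24, 3.3e-05) and FGF11 (-1.85 ± 0.30, 0.00123, detected on 1 of 3 normoxia solvent arrays), all raised by hypoxia on shared solvent arrays. KISS1R went from 5.76 ± 0.40, near background, to 7.12 ± 0.16 log2 (SD, n = 3) with vorinostat in normoxia and from 9.60 ± 0.19 to 8.78 ± 0.31 in hypoxia. The difference was positive in the cytochrome P450 genes CYP1B1 (1.80 ± 0.29, adjusted p = 0.00123) and CYP1A1 (1.69 ± 0.33, adjusted p = 0.00749) and in LHX1 (1.46 ± 0.22, adjusted p = 6.3e-04), a homeobox gene. With the 12 arrays of DU145 alone NDRG1 (adjusted p = 0.0556, 3.2e-06 to 0.0556 over the alternatives), FGF11 (0.0769, 3.0e-06 to 0.0769 over the alternatives) and LHX1 (0.101, 8.1e-05 to 0.101 over the alternatives) were not called. In DU145 90 genes were called (26 higher, 64 lower), and the count fell to 49 to 58 without hypoxia solvent 3 (49), hypoxia vorinostat 1 (57) or 3 (58), normoxia solvent 2 (54) or 3 (57), or normoxia vorinostat 2 (55). With the replicate block 193 genes were called. On simulated data without any such difference and without pairing the mean number of calls was at most 5.8 and the highest 16. Among the glycolysis enzymes, 0 were higher and 2 lower of 18, or 0 and 6 adjusted over the list alone (median log2 difference -0.26, camera adjusted p = 5.7e-04, adjusted p = 0.111 with an estimated correlation). Among the hypoxia-induced genes, 1 was higher and 3 lower of 24, or 2 and 4 adjusted over the list alone (median log2 difference -0.17, camera adjusted p = 0.0308, adjusted p = 0.443 with an estimated correlation). Of the cholesterol synthesis genes, 0 were higher and 0 lower of 17, or 0 and 1 adjusted over the list alone (median log2 difference -0.30, camera adjusted p = 5.7e-04, adjusted p = 0.184 with an estimated correlation). Of the homologous recombination and Fanconi anaemia genes, 0 were higher and 0 lower of 20 (median log2 difference 0.32, camera adjusted p = 0.00139, adjusted p = 0.0591 with an estimated correlation).

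In 22Rv1 the difference was negative in MCM2 (-1.66 ± 0.23, adjusted p = 1.3e-04), a replicative helicase subunit, RAB31 (-1.58 ± 0.24, adjusted p = 3.5e-04), a vesicle GTPase, and SNCB (-1.52 ± 0.24, adjusted p = 4.0e-04), a synuclein. MCM2 went from 10.51 ± 0.05 to 9.48 ± 0.17 log2 (SD, n = 3) with vorinostat in normoxia and from 10.07 ± 0.14 to 7.38 ± 0.21 in hypoxia. A positive difference was found in UPK1A (1.19 ± 0.24, adjusted p = 0.0104), STC1 (1.10 ± 0.23, adjusted p = 0.0129) and MYOD1 (1.01 ± 0.20, adjusted p = 0.00534). The call of STC1 ended with median scaling (adjusted p = 0.218, 4.8e-04 to 0.218 over the alternatives) and without hypoxia solvent 3 (0.0512), hypoxia vorinostat 1 (0.0584) or normoxia solvent 3 (0.0588). UPK1A was not called with median scaling (0.261), cyclic loess (0.0529) or the 12 arrays of 22Rv1 alone (0.0837, 4.0e-04 to 0.261 over the alternatives), MYOD1 with the 12 arrays alone (0.0679), the authors' processed values (0.0657) or no background correction (0.0578, 2.8e-04 to 0.0679 over the alternatives), and SNCB with the authors' processed values (0.300) or no background correction (0.453, 3.3e-06 to 0.453 over the alternatives). Among the DNA replication genes, 0 were higher and 15 lower of 37, or 0 and 22 adjusted over the list alone (median log2 difference -0.55, camera adjusted p = 1.2e-37, adjusted p = 3.0e-05 with an estimated correlation). Among the homologous recombination and Fanconi anaemia genes, 0 were higher and 2 lower of 20 (median log2 difference -0.27, camera adjusted p = 4.4e-05, adjusted p = 0.00410 with an estimated correlation). Of the DNA damage signalling genes, 0 were higher and 0 lower of 11, or 0 and 2 adjusted over the list alone (median log2 difference -0.23, camera adjusted p = 0.0215, adjusted p = 0.105 with an estimated correlation), and 0.0616 with median scaling. In 22Rv1 90 genes were called (18 higher, 72 lower), with at most 3 calls on simulated data without a difference (at most 14 with 1 weight per line, where the real count was 241). The share called higher was 20%, or 5.56% with median scaling, which moved the median difference of all genes to -0.12.

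In PC-3 7 genes were called, 1 higher and 6 lower, against means of 7.5 to 20.7 on data simulated without any difference (2.3 to 4.35 with 1 weight per line). The simulations leave out the replicate number. With the replicate block 46 genes were called, so the count depends on the model. At an unadjusted p under 0.05 limma gave 1012 genes. Median scaling moved the median difference of all genes to -0.10 and the share called higher from 14.3% (1 of 7) to 0% (0 of 2). The largest differences were ZNF784 (1.11 ± 0.20, adjusted p = 0.0230) and SCNN1G (-1.08 ± 0.22, adjusted p = 0.0429). ZNF784 was not called with array weights (0.114), median scaling (0.0765), 1 weight per line (0.135) or the 12 arrays of PC-3 alone (0.689, 0.00894 to 0.689 over the alternatives), nor without hypoxia solvent 2 (0.0509) or 3 (0.0615), hypoxia vorinostat 2 (0.0939), normoxia solvent 3 (0.0832), or normoxia vorinostat 2 (0.0773) or 3 (0.0571). SCNN1G was not called with no filter (0.0585), 1 weight per line (0.181) or the 12 arrays alone (0.689, 0.0128 to 0.689 over the alternatives), nor without hypoxia solvent 1 (0.106), 2 (0.0618) or 3 (0.0615), hypoxia vorinostat 1 (0.0764), 2 (0.0589) or 3 (0.0720), normoxia solvent 1 (0.0564) or 3 (0.115), or normoxia vorinostat 1 (0.0732) or 2 (0.0902). The count was 2 without hypoxia solvent 1 or 3, hypoxia vorinostat 2 or normoxia solvent 3, 3 without hypoxia vorinostat 1, 0 without normoxia vorinostat 2, and 11, 15 and 18 without hypoxia solvent 2, hypoxia vorinostat 3 and normoxia solvent 2. Of the hypoxia-induced genes, 0 were higher and 1 lower of 24, or 0 and 4 adjusted over the list alone (median log2 difference -0.31, camera adjusted p = 1.0e-08, adjusted p = 0.0154 with an estimated correlation).

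The study's aim was a signature of the line that vorinostat radiosensitised, so the drug effect was also compared between lines (DU145 minus PC-3, and DU145 minus 22Rv1). The effect on TXNIP, called in DU145 alone, was higher there than in PC-3 (difference 2.48 ± 0.21, adjusted p = 2.7e-10) and than in 22Rv1 (2.31 ± 0.21, adjusted p = 4.7e-10). The rise in HDAC1 was also larger in DU145 than in PC-3 (0.94 ± 0.08, adjusted p = 4.2e-10) and than in 22Rv1 (0.84 ± 0.08, adjusted p = 1.9e-09). Of the histone genes, 16 were higher and 0 lower of 22, or 18 and 0 adjusted over the list alone (median log2 difference 0.97, camera adjusted p = 1.6e-06, adjusted p = 0.335 with an estimated correlation) against PC-3. They include H2AC8 (1.78 ± 0.23) and H2BC4 (1.58 ± 0.23). Against 22Rv1, 14 were higher and 1 lower of 22 (median log2 difference 0.89, camera adjusted p = 4.3e-05, adjusted p = 0.275 with an estimated correlation). They include H2AC8 (1.91 ± 0.23) and H4C8 (1.86 ± 0.29). Of the metallothioneins, 8 were higher and 0 lower of 8 (median log2 difference 1.25, camera adjusted p = 9.6e-08, adjusted p = 0.128 with an estimated correlation) against PC-3. They include MT1M (2.51 ± 0.18) and MT3 (1.97 ± 0.19). In DU145, 3 of the 22 histone genes, H2AC8 among them, and 3 of the 8 metallothioneins, MT3 among them, were above background in 1 group only, and in 22Rv1 6 histone genes were in neither group and 1 in 1 group only. H4C8 was above background on no vorinostat array of 22Rv1. These differences and medians are fitted values, not bounds.

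The drug effect on 4 lists of proliferation and repair genes was less negative in DU145 than in 22Rv1, in the first 2 also with an estimated correlation. Of the DNA replication genes, 33 were higher and 0 lower of 37, or 34 and 0 adjusted over the list alone (median log2 difference 0.74, camera adjusted p = 2.2e-15, adjusted p = 0.00538 with an estimated correlation). They include TK1 (1.87 ± 0.09) and RRM2 (1.74 ± 0.19), which supply nucleotides. Of the homologous recombination and Fanconi anaemia genes, 13 were higher and 0 lower of 20 (median log2 difference 0.60, camera adjusted p = 3.4e-05, adjusted p = 0.00538 with an estimated correlation). They include EXO1 (1.63 ± 0.11) and BLM (1.32 ± 0.19). Among the G2 and mitosis genes, 24 were higher and 1 lower of 34, or 26 and 1 adjusted over the list alone (median log2 difference 0.46, camera adjusted p = 2.7e-06, adjusted p = 0.275 with an estimated correlation). They include CDC25C (1.18 ± 0.19) and CDC25A (1.07 ± 0.13). Of the DNA damage signalling genes, 6 were higher and 0 lower of 11, or 7 and 0 adjusted over the list alone (median log2 difference 0.54, camera adjusted p = 0.0144, adjusted p = 0.138 with an estimated correlation). They include MDC1 (0.86 ± 0.15) and CHEK2 (0.83 ± 0.13). The mesenchymal markers went the other way: 2 were higher and 9 lower of 13 (median log2 difference -0.65, camera adjusted p = 0.00502, adjusted p = 0.178 with an estimated correlation). They include CAV1 (-2.41 ± 0.20) and, upwards, SNAI2 (1.54 ± 0.21). Of the glycolysis enzymes, 0 were higher and 7 lower of 18 (median log2 difference -0.22, camera adjusted p = 0.00502, adjusted p = 0.178 with an estimated correlation). They include PFKP (-0.88 ± 0.14) and GPI (-0.68 ± 0.11). Among the hypoxia-induced genes, 4 were higher and 11 lower of 24, or 4 and 12 adjusted over the list alone (median log2 difference -0.35, camera adjusted p = 0.0464, adjusted p = 0.366 with an estimated correlation), and 0.0724 with median scaling.

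Against PC-3, 2 further lists differed. Of the NF-kappaB and inflammatory genes, 1 was higher and 7 lower of 17 (median log2 difference -0.43, camera adjusted p = 0.0115, adjusted p = 0.541 with an estimated correlation). They include IL1B (-1.81 ± 0.14) and, upwards, CCL20 (1.71 ± 0.23). Among the glycolysis enzymes, 1 was higher and 8 lower of 18, or 1 and 9 adjusted over the list alone (median log2 difference -0.22, camera adjusted p = 0.0115, adjusted p = 0.335 with an estimated correlation). They include HK2 (-0.84 ± 0.16) and, upwards, ALDOC (0.67 ± 0.18). The drug effect differed in 3827 genes between DU145 and PC-3 (2188 higher in DU145, 1639 lower) and in 4876 between DU145 and 22Rv1 (2622 higher, 2254 lower). With median scaling the share higher moved from 57.2% to 75.6% and from 53.8% to 66.6%, and the median difference of all genes to PC-3 moved to 0.12. In simulations 5.44% to 5.57% and 2.40% to 2.63% of such calls were false.

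DU145-specific genes were called the same way in DU145 at both oxygen levels, with a called difference that way from each other line. They may also move in those lines. There were 1554, of which 951 rose and 603 fell (925 and 232 of 1157 with median scaling), and 1003 of them changed by at least 1.5-fold at both oxygen levels, a limit added after the count was seen. Among the largest rises by fitted value were those of TMSB15A, AADACP1, VGF, CCNA1 and HLA-DMB, named for DU145, and of AKR1C3 (3.26 ± 0.13), SEPTIN4 (at least 5.97-fold higher), CRIP2 (3.17 ± 0.14, detected on 2 of 6 solvent arrays) and IL24 (3.16 ± 0.22, detected on 3 of 6 solvent arrays). Among the largest falls were those of FGB, NRP1, CAP2 and MALL and of HAS3 (-2.01 ± 0.18), PLD6 (-2.01 ± 0.12, detected on 4 of 6 vorinostat arrays), DUS3L (-2.01 ± 0.14), PRKAR1B (-1.97 ± 0.19, detected on 1 of 6 vorinostat arrays) and TRIP6 (-1.96 ± 0.15), with adjusted p = 4.1e-10 or less. The count was 1328 to 1635 when each of the 36 arrays was left out in turn. With the same drug effect simulated in each line, 0 met the rule, which cannot give the false share of the 1554.

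The lines were compared without drug, in normoxia with solvent, 3 arrays against 3. DU145 expressed UCHL1 (at least 222-fold higher) and CAVIN1 (at least 199-fold higher), CTNNA1 (at least 73.8-fold higher) and PAFAH1B3 (at least 40.5-fold higher) more than PC-3, with MT1E (6.76 ± 0.14) and EFEMP1 (5.86 ± 0.28, detected on 2 of 3 PC-3 arrays), with adjusted p = 1.3e-17 or less. It expressed MSMP (at least 403-fold lower), SRGN (at least 197-fold lower), PI3 (at least 190-fold lower) and PHACTR3 (at least 65.1-fold lower) less, with IFITM2 (-6.89 ± 0.14, detected on 2 of 3 DU145 arrays), with adjusted p = 4.2e-26 or less, which encode a secreted microseminoprotein, a proteoglycan, an elastase inhibitor, a phosphatase regulator and an antiviral membrane protein. Of the interferon-stimulated genes, 2 were higher and 19 lower of 24 (median log2 difference -1.51, or -1.19 with bounds, camera adjusted p = 0.00105, adjusted p = 0.365 with an estimated correlation). They include IFITM3 (-6.46 ± 0.14, detected on 2 of 3 DU145 arrays) and, upwards, HLA-B (2.96 ± 0.15). Among the mesenchymal markers, 2 were higher and 8 lower of 13 (median log2 difference -0.82, or -1.01 with bounds, camera adjusted p = 0.0296, adjusted p = 0.365 with an estimated correlation). They include CDH2 (at least 37.4-fold lower) and SNAI2 (at least 14.7-fold lower).

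Compared with 22Rv1, DU145 expressed UCHL1 (at least 223-fold higher), AXL (at least 87.1-fold higher), PLAU (at least 81.6-fold higher) and S100A16 (at least 61.7-fold higher) more, with CAV1 (6.39 ± 0.20, detected on 1 of 3 22Rv1 arrays), with adjusted p = 2.7e-22 or less. It expressed KLK4 (at least 202-fold lower), CTAG2 (at least 81.4-fold lower), COLEC12 (at least 61.6-fold lower) and ELF5 (at least 55.1-fold lower) less, with LXN (-7.73 ± 0.22, detected on 2 of 3 DU145 arrays), with adjusted p = 2.1e-23 or less, which include a prostate kallikrein, a cancer-testis antigen and an epithelial transcription factor. Of the androgen target genes, 1 was higher and 11 lower of 13 (median log2 difference -1.38, camera adjusted p = 0.00122, adjusted p = 0.0101 with an estimated correlation). They include HOXB13 (at least 10.7-fold lower) beside KLK4. Of the hypoxia-induced genes, 15 were higher and 2 lower of 24 (median log2 difference 1.03, or 1.33 with bounds, camera adjusted p = 4.0e-04, adjusted p = 0.151 with an estimated correlation). They include BHLHE40 (3.44 ± 0.11) and ADM (2.38 ± 0.17). Of the mesenchymal markers, 7 were higher and 3 lower of 13, or 7 and 4 adjusted over the list alone (median log2 difference 1.70, or 3.76 with bounds, camera adjusted p = 0.0124, adjusted p = 0.259 with an estimated correlation). Of the NF-kappaB and inflammatory genes, 11 were higher and 2 lower of 17 (median log2 difference 1.78, or 1.32 with bounds, camera adjusted p = 0.00122, adjusted p = 0.259 with an estimated correlation). They include CXCL8 (at least 45.2-fold higher) and CXCL2 (at least 4.32-fold higher). There were 7698 genes called between DU145 and PC-3 (3871 higher in DU145, 3827 lower) and 8010 between DU145 and 22Rv1 (3754 higher, 4256 lower). The groups did not overlap in 62.8% and 69.7% of the genes, against 10% by chance. With median scaling the share higher against 22Rv1 moved from 46.9% to 34.4% and the median difference of all genes to -0.20.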

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

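Tests chosen after the result was seen were the weight per cell line, the other scalings of the ratio of gene counts, the DNA replication genes as a sign of S phase, and the histone genes above background in 22Rv1. The other tests were chosen before.

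The effect of vorinostat differed between oxygen levels, by a test of the difference itself, in 90 genes in DU145, 7 in PC-3 and 90 in 22Rv1. Rearranging the residuals of a model without that difference gave as many genes in 6 of 100 arrangements for DU145 (highest other 334) and in 32 of 100 for PC-3 (highest other 857), so chance is not excluded for either, and arrangements with so many genes point to a structure of the samples that the model leaves out. The arrangements do not keep the replicate number. In 22Rv1 only the real one did, 1 of 100, the lowest share possible (highest other 11). Differences between oxygen levels were also called for the hypoxia-induced genes in PC-3 (median log2 difference -0.31) and for the DNA replication genes (-0.55) and the homologous recombination and Fanconi anaemia genes (-0.27) in 22Rv1.

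The drug effect in DU145 differed from PC-3 in 3827 genes and from 22Rv1 in 4876, and 1554 met the DU145-specific rule. In each case 1 of 100 arrangements, the real one, gave as many genes, with 203, 2919 and 29 as the highest other, so chance is excluded. Between DU145 and 22Rv1 the DNA replication genes (median log2 difference 0.74) and the homologous recombination and Fanconi anaemia genes (0.60) differed with the estimated correlation as well.

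Genes moved the same way at both oxygen levels were tested by splitting arrays within each level. Of 100 splits only the real one gave as many genes in each line: 3754 in DU145 (highest other 3), 2166 in PC-3 (42) and 2995 in 22Rv1 (0). The others mix drug and solvent arrays and cannot exclude a batch difference. For 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real split and the highest other gave, for vorinostat in normoxia and hypoxia, 5035 and 29, 5107 and 4 in DU145, 3176 and 81, 3506 and 20 in PC-3, and 3872 and 0, 4125 and 2 in 22Rv1. Hypoxia gave 1823 and 36 in DU145, 2086 and 50 in PC-3, and 2492 and 0 in 22Rv1. The lines without drug gave 7698 and 3 against PC-3, and 8010 and 0 against 22Rv1.

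Among the 4875 detected probes with no single gene symbol, which enter no comparison of genes, vorinostat changed 693 at both oxygen levels in DU145 (332 higher, 361 lower), 295 in PC-3 (153 and 142) and 434 in 22Rv1 (234 and 200).

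More genes moved at both oxygen levels in DU145 (3754) than in 22Rv1 (2995), a ratio of 1.25. Normalization between arrays is argued against, since the lowest ratio under 4 other scalings was 1.21. With 1 weight per cell line, which lets the lines differ in spread, the ratio was 0.924 (3604 and 3899 genes), and it was also below 1 with array weights (0.943) and with the 12 arrays of each line alone (0.872). The unequal spread of the lines may therefore account for the order. The counts do not rank the lines by the size of their response, and a biological difference between them stays open and untested in this respect.

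Histone genes rose more with vorinostat in DU145 than in PC-3 and 22Rv1 (median log2 difference 0.97 and 0.89). Normalization is argued against, as the lowest median difference under 5 other scalings was 0.54. More cells in S phase, when histone genes are transcribed, would raise the DNA replication genes. Their median log2 change was -0.32 (standard error 0.091) in DU145, and the difference was -0.090 (0.066) from PC-3 and 0.74 from 22Rv1. In 22Rv1 they fell (-1.17), while the 13 histone genes above background on each solvent array had a median of -0.055 (0.14). The drug may act on replication genes itself, so they cannot decide on S phase, which stays open. The standard errors take genes as independent. Signal near background is argued against as the whole cause of the difference from 22Rv1, which was 0.67 (0.21) in these 13 genes. Histone genes are near-identical paralogs and the probe sequences were not used here, so signal shared between paralogs stays open, and so do the polyadenylation of histone transcripts and any biological difference between the lines. The list's call did not hold with an estimated correlation (adjusted p = 0.335 and 0.275), so the shift may belong to 1 set of genes that vary together.

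DNA replication genes fell further with vorinostat in hypoxia than in normoxia in 22Rv1 (median log2 difference -0.55, 37 genes). A single array is argued against: the highest adjusted p with 1 of 12 arrays left out was 1.57e-32. Signals near background are argued against as well, since the 18 brighter members had a median of -0.67 (standard error 0.13, 16 below 0) and the other 19 a median of -0.54. A joint action of low oxygen and vorinostat on the transcription of replication genes is 1 hypothesis, and fewer cells in S phase may give the same picture, which arrays of whole cultures cannot separate. Whether the replicates are separate cultures is not stated, so a difference between culture batches stays open.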

How the results depend on the processing

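Chosen after the data were seen were 1 weight per cell line and the 1.5-fold limit. Of the 20 counts of called genes, those within 1.5 times the reported value numbered 20 without a filter, 19 with the authors' processed values, no background correction, cyclic loess and every probe tested, 17 with array weights, 16 with 1 weight per line, 15 with median scaling, 14 with detection on all arrays, 9 of 15 with the 12 arrays of a line alone, 18 of 18 with quantile normalization within lines (not applied between lines) and 18 with the replicate block. A block for the slide was not run, since the files name no slide.

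The counts that moved are given by setting. Hypoxia in 22Rv1 (2492) gave 4184 with array weights, 3947 with 1 weight per line and 3786 with its 12 arrays alone. With median scaling, hypoxia gave 888 in DU145 (1823) and 1172 in PC-3 (2086), and vorinostat at both oxygen levels in PC-3 (2166) gave 1438. With the 12 arrays of PC-3 alone, hypoxia gave 1048, vorinostat in normoxia (3176) 2103 and vorinostat at both oxygen levels 1418. The cause was not tested. With detection on all 36 arrays fewer genes were tested, and the count was 4987 (DU145 against 22Rv1) and 4888 (against PC-3) without drug and 3191 for the drug effect between DU145 and 22Rv1. A limit of 1.5-fold left 1003 of the 1554 DU145-specific genes, by its construction.

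The difference of the drug effect between oxygen levels moved most. In 22Rv1 (90) it gave 269 genes with array weights, 241 with 1 weight per line and 44 with detection on all arrays. In DU145 (90) it gave 55 with detection on all arrays, 14 with median scaling, 56 with 1 weight per line, 4 with its 12 arrays alone and 193 with the replicate block. In PC-3 (7; limma, 1012 at an unadjusted p under 0.05) it gave 4 with array weights, 29 with the authors' processed values, 29 with no background correction, 14 with cyclic loess, 12 with detection on all arrays, 13 with every probe tested, 2 with median scaling, 46 with the replicate block, and 0 with 1 weight per line and with its 12 arrays alone. The cause was not tested. The replicate block moved no other count by over 1.5 times; 11, 12 and 11 of the 12 arrays of DU145, PC-3 and 22Rv1 correlated best with their own replicate number, a hint from the data and not the design.

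With 1 array left out in turn, where the group left with fewer arrays is assumed to vary like the others, the counts ranged as follows. Vorinostat gave 4227 to 4879 and 4362 to 4899 in DU145 (normoxia and hypoxia), 2607 to 2914 and 2828 to 3373 in PC-3, 3152 to 3377 and 3458 to 3680 in 22Rv1, and at both levels 3291 to 3671, 1828 to 2115 and 2579 to 2795. Hypoxia gave 1293 to 1854, 1451 to 2322 and 1782 to 1977. The drug effect between lines gave 3504 to 3933 (PC-3) and 4617 to 4849 (22Rv1), the DU145-specific genes 1328 to 1635, and the lines without drug 7266 to 7377 (PC-3) and 7598 to 7738 (22Rv1). The difference between oxygen levels gave 49 to 106 in DU145, 64 to 87 in 22Rv1 and 0 to 18 in PC-3.

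Signs that reversed belong to genes that were not called under vorinostat, and the cause was not tested. HDAC6 in DU145 had a log2 change of 0.0059 with array weights, 0.040 with cyclic loess and 0.11 with median scaling, and -0.053 to 0.018 with 1 array left out. HDAC6 in 22Rv1 ranged from -0.030 to 0.077 with 1 array left out, and HDAC2 in 22Rv1 from -0.030 to 0.019, with 0.021 under cyclic loess. In PC-3 TXNIP had 0.031 with array weights and 0.046 with cyclic loess and ranged from -0.092 to 0.089, and VEGFA ranged from -0.17 to 0.054. In 3 lists not called by camera, fry called a change whose direction was opposite to the camera shift against other genes: apoptosis regulators between DU145 and 22Rv1 under vorinostat (adjusted p = 0.0453), and metallothioneins (0.0459) and neuronal genes (0.004945) between DU145 and PC-3 without drug.

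Of 770 named genes and comparisons, 72 lost their call with median scaling, 22 with no background correction, 22 with 1 weight per line, 21 with no filter, 16 with the authors' processed values, 12 each with array weights and cyclic loess, 6 with every probe, 2 with the replicate block, and 46 of 468 with the 12 arrays of a line. With 1 array left out 362 of 8814 lost it. The 325 list results include many that were not called and had no call to lose. With an estimated correlation 41 lost their call, which is more than kept it. With median scaling 3 lost it. The fry test, against no change and not against other genes, called 105 others in the same direction. With median scaling 6 gained a call: the 3 given for vorinostat, DNA replication genes between oxygen levels in PC-3, epithelial markers between DU145 and PC-3, and neuronal genes between DU145 and 22Rv1. Log2 changes of called named genes were smaller without background correction (median ratio 0.722 to the reported value, over 1.5 times smaller in 324 of 760) and with the authors' processed values (0.753, 287 of 760).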

Other observations

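Tests here were chosen before the result was seen, the genes TXNIP and HDAC1 after. The effects of vorinostat in normoxia and in hypoxia had a Pearson correlation across genes of 0.87 in DU145, 0.80 in PC-3 and 0.87 in 22Rv1 (rank correlation 0.81, 0.71 and 0.81). For hypoxia without drug the correlation between lines was 0.50 (DU145 and PC-3), 0.47 (DU145 and 22Rv1) and 0.50 (PC-3 and 22Rv1). DU145 and PC-3 had 342 rises and 413 falls in common and 16 genes in opposite directions, DU145 and 22Rv1 had 360, 367 and 34, and PC-3 and 22Rv1 had 342, 512 and 27. Genes are not independent replicates, so no p-value is given.

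Without drug, 2 genes stood far from the other lines, on arrays partly shared with their drug effect. TXNIP was lower in DU145 than in PC-3 (-4.82 ± 0.21, adjusted p = 1.5e-18) and than in 22Rv1 (-3.94 ± 0.21, adjusted p = 1.4e-16), and HDAC1 was lower as well (-1.21 ± 0.08, adjusted p = 7.4e-14 and -1.27 ± 0.08, adjusted p = 1.7e-14). Whether vorinostat moved DU145 genes in general towards the other lines was tested on arrays the 2 quantities do not share. Across 12360 genes the drug effect in normoxia had a Pearson correlation of -0.11 with the difference from PC-3 in hypoxia without drug and of -0.11 with that from 22Rv1 (rank correlations -0.11 and -0.08). Both values lie between the limits set beforehand, -0.2 or less for such a movement and above -0.1 against it, so the question stays open.

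The probe RNA28SN5 varied widely between replicates, at 12.56, 4.90 and 8.08 log2 on the 3 arrays of DU145 in normoxia with solvent.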
